A study of Mus musculus with 2 samples.

How the data were processed

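H3K4me1, a histone H3 modification found at enhancers and on the flanks of active promoters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq). The tissue was mouse forebrain at embryonic day 10.5. Per the labels, the 2 samples are biological replicates of 1 group, each a mixed-sex pool of B6NCrl embryos. Replicate 1 pooled 69 embryos and replicate 2 pooled 51, and the size range was 300 to 500 bp for both. No other tissue, age or mark is part of the series, so no difference between groups was tested.

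The authors deposited 4 peak lists on the mm10 build: one called on replicate 1, one on replicate 2, one on the pooled replicates, and one of replicated peaks. Per the deposited notes, the replicated list derives from the other lists. The peak caller, its version and the overlap rule behind the replicated list are not given in the sources used here. Per the same notes, the replicate 1 and pooled lists each drew on 2 further files and the replicate 2 list on 1. The role of those files is not stated, so it is unknown whether the replicates were called against the same background. Each peak carries the authors' signal value, which is a height on a scale not stated in the sources used here. It also carries the −log10 p and −log10 q that the authors deposited, and a summit position. These are each peak's own values and were used only to describe, rank or filter peaks, or, for pairs of overlapping peaks, to compare the replicates. No peak in the deposited lists had a −log10 p below 2. The lists give no read counts, so the sequencing depth of each sample is unknown and no counting interval on a signal value can be given.

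Peaks on chromosomes 1 to 19 and X were used. This left out 1 peak of the replicated list, 4 of the replicate 1 list, 1 of the replicate 2 list and 4 of the pooled list. Chromosome names and lengths were checked against the GRCm38.p6 sequence, which has the mm10 coordinates, and 0 peaks ran past a chromosome end. Gene models came from GENCODE release M21. All symbols of the gene lists were found in it. Coordinates are 1-based.

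Peaks were called shared between replicates when at least 50% of either peak was overlapped. Chance overlap was the mean over 100 random circular shifts of the replicate 2 list within each chromosome. The replicated list was the main set for all other results. Covered bases were divided into promoter (within 1 kb of a transcript start), exon, intron and intergenic, in that order. The start of a gene was its annotated 5′ end, and starts were called CpG-rich where the CpG observed/expected ratio of the surrounding 1 kb was at least 0.6. Peaks over 2 kb from every transcript start were called distal. Domains were made by joining replicated peaks at most 1 kb apart.

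For 21728 protein-coding genes, the number of kb covered by peaks was counted within 50 kb on each side of the start. A peak counts for every gene whose window it touches, so close neighbours share values. Genes of a list with starts at most 100 kb apart were joined into 1 locus. The median over loci was compared with 10000 random lists of 1 gene per locus, matched on gene length (10 classes) and on the number of starts in the window (5 classes). The two-sided permutation p was adjusted by the Benjamini-Hochberg method over 19 lists and called at 0.05. The smallest p these lists can give is 0.0002. The design fixed beforehand spoke of random lists of the same number of genes, and drawing 1 gene per locus keeps large clusters from counting many times over. The forebrain list was set against 6 other lists by permuting list labels over loci, exactly for the Hox list and with 100000 resamples otherwise.

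Motif matches were counted on both strands of distal peaks and of equally wide flanks 10 kb to each side that lay outside pooled peaks. From each log2 ratio the mean of up to 20 shuffled motifs with the same base composition and CpG count was subtracted. Annotation classes, start profiles and motifs were tested by two-sided sign-flip permutation over the 20 chromosomes with 100000 resamples, for which 1e-05 is the smallest p possible. These p-values, and those of the gene lists, treat chromosomes or genes as the units. They describe this pair of libraries and do not measure variation between embryos. A mean ± SD with n = 2 is over the replicates' own peak lists. The replicated list follows the bounds of the pooled peaks and can cover more than either replicate.

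Each procedure was tested on simulated data. Of 20 random gene lists without an effect 0 were called, and of 8 lists given 8 kb per gene 8 were called. These lists were run on peaks shifted at random along each chromosome, which breaks the relation of peaks to genes and GC content. False calls from such a relation are therefore not covered. The sign-flip test called 9 of 200 null sets and 200 of 200 shifted ones. The test between lists called 3 of 40 null pairs and 40 of 40 pairs of lists set 30 kb apart, each pair with 12 and 4 simulated loci. The main differences reported below are smaller than 30 kb, and differences of their size were not simulated. The overlap rules recovered 1000 of 1000 shifted peaks and 0 of 1000 displaced ones. A planted motif was called and 0 of 15 other motifs were, in random sequence with the same base composition in regions and controls. The distal peaks and their flanks differ in GC content (48.3% and 43.6%). The simulation therefore does not cover false calls from such a difference.

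The genes named below follow a rule set before the data were examined. For the forebrain, progenitor and early neuron lists it takes the 6 members with the most and the 2 with the least covered sequence. For the other lists, apart from the receptor families, it takes the 3 with the most and the 1 with the least. It adds the 10 genes with the most covered sequence genome-wide, leaving out any that starts within 100 kb of one already taken, the 5 longest domains, the 5 peaks of highest signal, the 3 strongest peaks found in only 1 replicate, and 15 named loci. The alternatives tried were other overlap rules, stricter peak filters, the pooled list, each replicate alone, other windows, measures and matching, other control regions for motifs, and no shuffle correction. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9.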

Results

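The data are H3K4me1 peak lists from forebrain dissected at embryonic day 10.5, when the telencephalon and diencephalon are being patterned and the first neurons appear. The 2 biological replicates, pools of 69 and 51 embryos, form 1 group. The list of replicate 1 held 231895 peaks covering 169.2 Mb, which is 6.61% of the sequenced bases of chromosomes 1 to 19 and X. That of replicate 2 held 186970 peaks covering 142.7 Mb, or 5.58%. The pooled list held 227130 peaks over 186.7 Mb. The replicated list held 165333 peaks over 171.0 Mb, or 6.68%, with a median width of 700 bp and a longest peak of 26043 bp. Read depth is unknown, so the lower number in replicate 2 cannot be set against its depth.

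The first comparison was between the replicates. The strongest H3K4me1 peaks were found in both pools of forebrain, and the peaks found in only 1 pool were weak and narrow. Of the strongest 10% of replicate 1 peaks by q, 99.98% were found in replicate 2, and of the strongest 10% of replicate 2 all 18697 were found in replicate 1. In the weakest 10% these shares were 23.8% and 52.2%. Over all peaks, 62.3% of those of replicate 1 (95% Wilson interval 62.1 to 62.5) and 81.0% of those of replicate 2 (80.8 to 81.1) were shared. The intervals cover counting error only and treat peaks as independent.

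Randomly shifted lists shared 7.56% ± 0.20 (SD, 100 shifts) of replicate 1 peaks and 9.24% ± 0.24 of replicate 2 peaks. Shared bases made up 63.1% of the union, against 3.26% ± 0.10 after shifting. When at least 50% of both peaks had to overlap, the shares fell to 45.9% and 56.9%. Across 177994 overlapping pairs of peaks, the authors' signal values of the replicates had a Spearman correlation of 0.54. This correlation is across peaks, which are not independent replicates.

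**Figure D1:**
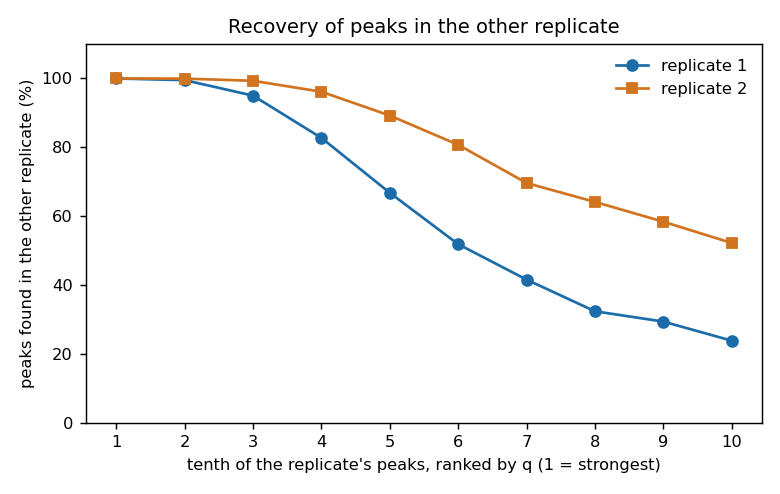
Share of each replicate's peaks found in the other replicate (y axis, %) in 10 equal classes ranked by the authors' q (x axis, 1 is the strongest). Recovery falls from 99.98% to 23.8% for replicate 1 (circles) and from 100% to 52.2% for replicate 2 (squares).

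Peaks without any overlap in the other replicate numbered 77633 in replicate 1 (33.5%) and 27693 in replicate 2 (14.8%). Their median widths were 247 and 257 bp, against 649 and 557 bp for the peaks with an overlap. They lay farther from gene starts, with median distances of 51.9 and 38.4 kb, against 34.1 and 35.4 kb for the peaks with an overlap. The strongest peak found only in replicate 1 had a signal value of 6.38 and lay on chromosome 6 at 146627945 to 146628681, nearest to the start of Med21 at 13.9 kb. The next lay on chromosome 11 at 112307488 to 112307951 with a signal of 6.10, nearest to Sox9, a progenitor and neural crest regulator whose start is 474.3 kb away. A peak on chromosome 14 at 33335187 to 33335828 nearest to Mapk8 followed with 5.85. In replicate 2 the strongest such peaks were nearest to Sdc3 on chromosome 4 at 130840225 to 130840728 (signal 5.34), Med13l on chromosome 5 at 119045093 to 119045500 (5.34) and 1700029H14Rik on chromosome 8 at 13562071 to 13562490 (4.98).

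The authors' replicated list holds 72.8% of the pooled peaks. Of its peaks, 29828 did not overlap peaks of both replicates by at least 1 bp, and 47483 were not covered to at least 50% by each replicate. Results on the replicated list were therefore also computed on the 117850 of its peaks that each replicate covered to at least 50%, a set chosen after seeing the data.

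The second comparison asked where in the genome the mark lay. H3K4me1 in embryonic forebrain was enriched at promoters, and most peaks lay away from gene starts. Promoters, within 1 kb of a transcript start, took 19.2% of covered bases and make up 6.13% of the genome, a log2 ratio of 1.64 ± 0.21 (SD over 20 chromosomes). Introns took 48.1% against 39.4% of the genome (log2 ratio 0.29 ± 0.11) and exons 4.31% against 3.27% (0.40 ± 0.21). Intergenic sequence took 28.4% against 51.2% (-0.85 ± 0.12). Each class moved in its direction on 20 of 20 chromosomes, with an adjusted sign-flip permutation p of 1e-05, the smallest possible. In the replicates' own lists the promoter share was 18.2% and 20.4%.

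Of the replicated peaks, 10.1% contained a transcript start and these were the widest, with a median of 1434 bp and a median signal of 4.90. Distal peaks, over 2 kb from every start, numbered 119913, or 72.5%, with a median width of 630 bp and a median signal of 3.11. They include the 11.9% of all peaks that lay over 50 kb from any start.

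Gene starts were split by CpG content, because CpG-rich promoters are mostly those of broadly expressed and developmental genes. At the 10058 CpG-rich starts the mark dipped at the start and rose on both sides. A peak covered 35.1% of these starts, 61.7% of positions 0.5 kb upstream and 76.7% of positions 1 kb downstream. At the 11670 CpG-poor starts there was no dip, and coverage was highest at the start itself, at 31.0%. At 97.7% of CpG-rich and 52.8% of CpG-poor starts, at least 1 of the positions at 0.5 kb steps within 5 kb lay inside a peak. Peaks lying between these positions were not counted.

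The tested offset was 1.5 kb. There, 68.3% of CpG-rich genes were covered downstream and 30.02% upstream, so that only the downstream side exceeded the start. The mean of both sides exceeded the start by 14.1 ± 4.24 percentage points (SD over chromosomes), on 20 of 20 chromosomes, with an adjusted sign-flip permutation p of 1e-05, the smallest possible. At CpG-poor genes 18.9% were covered downstream and 8.88% upstream, and the mean of both sides minus the start was -17.1 ± 4.83 points, below 0 on 20 of 20 chromosomes, with the same adjusted permutation p of 1e-05. Splitting at a CpG ratio of 0.4 reduced the CpG-rich difference to 3.05 points, still above 0 on 16 of 20 chromosomes by the permutation test (adjusted p = 0.00097).

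**Figure D2:**
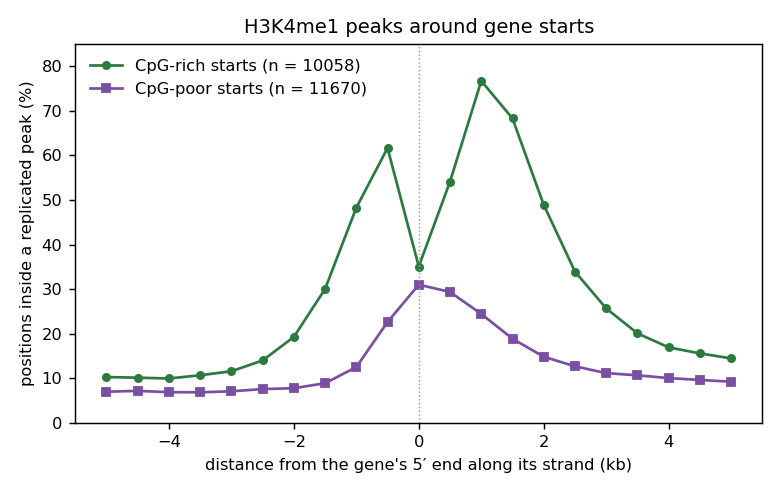
Share of gene starts, and of positions at 0.5 kb steps along the gene's strand (x axis, kb), that lie inside a replicated peak (y axis, %), for 10058 CpG-rich (circles) and 11670 CpG-poor (squares) starts. The CpG-rich profile dips to 35.1% at the start between maxima of 61.7% and 76.7%, and the CpG-poor profile peaks at 31.0% at the start.

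The third comparison asked which genes the mark surrounded. The most densely marked groups were the transcription factors that pattern the forebrain and the genes of neural progenitors. The 35 forebrain factors had a median of 29.8 kb of peaks within 50 kb of the start, against 5.03 kb in matched random lists (central 95%, 2.32 to 8.67), and the 32 progenitor genes had 29.5 kb against 6.04 kb. The median of all 21728 protein-coding genes was 7.60 kb. Every member of both lists had a peak in its window, and 27 of the 35 and 28 of the 32 were in the top 25% of all genes. In the replicates' own lists the medians were 27.7 ± 2.94 kb and 28.1 ± 0.77 kb (SD, n = 2). The list permutation test gave an adjusted p of 0.00042 for both.

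Among the forebrain factors, Nr2f2, an orphan nuclear receptor of the ventral and caudal forebrain, had the most (46.8 kb, and 43.8 ± 3.35 kb in the replicates, SD, n = 2). Tcf7l2, a WNT effector of the thalamus and caudal forebrain, followed with 46.2 kb (42.1 ± 2.68 kb). Nr2f1, a regulator of cortical area identity, had 41.0 kb and Pax6, which patterns dorsal telencephalon and eye, had 40.1 kb (37.2 ± 2.92 kb). The dorsal telencephalic factor Emx1 had 38.3 kb and Otx1 had 38.1 kb. The least covered were the ventral forebrain factor Nkx2-1 with 9.37 kb and the eye field factor Six6 with 6.90 kb, a value below the median of all genes.

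Among progenitor genes, the Notch receptors had the most, Notch1 with 54.7 kb (51.4 ± 2.56 kb) and Notch2 with 53.6 kb (49.7 ± 0.68 kb). The zinc finger factors Zic1 and Zic5, active in the dorsal midline, had 47.3 and 47.0 kb. Nes, the intermediate filament of progenitors, had 46.6 kb and the RNA-binding protein Msi2 had 46.2 kb. Prom1 (11.4 kb) and Sox3 (10.9 kb), the latter on chromosome X, had the least. The 31 early neuron genes had a lower median, 14.5 kb against 6.11 kb in random lists, with 14 in the top 25% (adjusted permutation p = 0.0011). By number of peaks this list was no longer called (adjusted permutation p = 0.17). Ebf3, a factor of early-born neurons, led with 38.3 kb (33.9 ± 0.78 kb). It was followed by the proneural factor Neurog1 (37.7 kb), Neurod2 (31.3 kb), Nhlh1 (29.1 kb), Lhx1 (23.8 kb) and Insm1 (22.6 kb). Stmn2, a tubulin regulator of growing axons, had 3.57 kb and St18 had 2.96 kb.

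Genes of the signalling pathways that pattern the forebrain were also surrounded by the mark. Medians were 21.8 kb for the SHH pathway (random lists 7.57 kb), 21.4 kb for the FGF pathway (6.04 kb) and 19.6 kb for the WNT pathway (5.91 kb), with 11 of 17, 16 of 22 and 24 of 32 members in the top 25%. Each had an adjusted list permutation p of 0.00042. Sfrp1, a secreted WNT antagonist, had 52.2 kb (48.7 ± 4.26 kb, SD, n = 2). Axin2, a WNT target and feedback inhibitor, had 47.6 kb and the receptor Fzd7 had 45.6 kb. In the SHH pathway the co-receptor Boc had 45.5 kb, the effector Gli3 43.2 kb (38.2 ± 6.82 kb) and the receptor Ptch1 42.8 kb. In the FGF pathway the inhibitor Il17rd had 39.6 kb, and the receptors Fgfr3 and Fgfr1 had 36.9 and 30.6 kb. The lowest members were Gpr161 with 6.83 kb, Rspo3 with 4.53 kb and Fgf13, on chromosome X, with 1.55 kb.

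Lists of other tissues and cell types divided. The head mesenchyme and neural crest list had a median of 19.0 kb against 5.35 kb in random lists (adjusted permutation p = 0.00042), with 17 of 29 members in the top 25%. It shares 6 members with other lists. Its most covered members were Dlx3 (38.2 kb), Alx4, a factor of craniofacial mesenchyme (37.6 kb), and Snai1, a driver of epithelial-mesenchymal transition (35.9 kb). Col3a1, a collagen of connective tissue, had 0.60 kb. Its replicate medians were 16.7 and 16.6 kb, while the median of all genes was 7.44 kb in replicate 1 and 6.31 kb in replicate 2. Alx4 had 28.3 kb in replicate 1 and 36.5 kb in replicate 2, and Dlx3 31.9 and 37.0 kb.

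The midbrain and hindbrain list (16.3 kb against 5.17 kb, adjusted permutation p = 0.00042), the limb bud list (13.1 against 6.01 kb, 0.014) and the endothelial list (14.6 against 8.27 kb, 0.042) were also called higher. The neural tube factors Pax7 (48.1 kb), Lmx1b (44.6 kb) and Pax3 (32.5 kb) led the first, Prrx2 (47.8 kb), Alx4 and the cartilage collagen Col2a1 (34.8 kb) the second, and Nos3 (37.7 kb), Egfl7 (33.4 kb) and Eng (33.0 kb) the third. Their lowest members were Atoh1 (7.70 kb), Meox2 (2.64 kb) and Emcn (1.42 kb). The window of Egfl7 overlaps that of Notch1. When random genes were matched also on the GC content of the window, these 3 lists were no longer called, with adjusted permutation p of 0.059, 0.24 and 0.50. The other 7 lists called higher passed that test too, with an adjusted permutation p of at most 0.0022.

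The olfactory receptor genes (1134 genes in 86 loci) had a median of 0.26 kb against 8.89 kb in random lists, and 921 of them had no peak in the window. The vomeronasal receptor genes (328 genes in 105 loci) had a median of 0 kb against 6.00 kb, and 280 had none. Both were called lower (adjusted permutation p = 0.00042). Neither call held with GC matching (adjusted permutation p = 0.71 and 0.10), where the smallest pool of matched genes for an olfactory locus held 7 genes.

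The remaining 7 lists were not called. Medians were 7.92 kb for heart, 5.72 kb for liver, 13.4 kb for blood, 11.1 kb for surface epithelium, 11.98 kb for later neurons and glia, 11.6 kb for housekeeping genes and 13.2 kb for the 4 Hox clusters, with adjusted permutation p from 0.068 to 0.99. Members of these lists ranged from among the highest values to none. Lyl1, an early blood factor, had 57.3 kb, Bcl11b, a factor of later cortical neurons, 48.9 kb, Camk2a 47.2 kb, the chaperone Hsp90ab1 41.5 kb and Prox1, a factor of liver that neural progenitors also use, 35.0 kb. The contractile genes Myl3 (26.8 kb), Myh6 (22.4 kb) and Myl7 (21.8 kb) led the heart list, Cldn7 (31.9 kb), Grhl3 (31.9 kb) and Wnt6 (28.5 kb) the epithelial list, and Hoxa5 (17.9 kb), Hoxd8 (17.4 kb) and Hoxa6 (17.1 kb) the Hox genes. Next to Prox1, Lyl1, Bcl11b and Hsp90ab1 stood Apoa2 (28.7 kb) and Foxa3 (18.4 kb) for liver, Nfe2 (32.7 kb) and C1qa (26.2 kb) for blood, Olig1 (35.7 kb) for glia, and Rplp0 (38.1 kb) and Eef2 (33.3 kb) for housekeeping. Hoxb13 had 4.79 kb, Trp63 2.66 kb and Hprt, on chromosome X, 1.81 kb. The sarcomeric gene Ttn had 1.19 kb, and the embryonic globin Hbb-y, the protease inhibitor Serpina1b and the neuropeptide Vip had none.

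**Figure D3:**
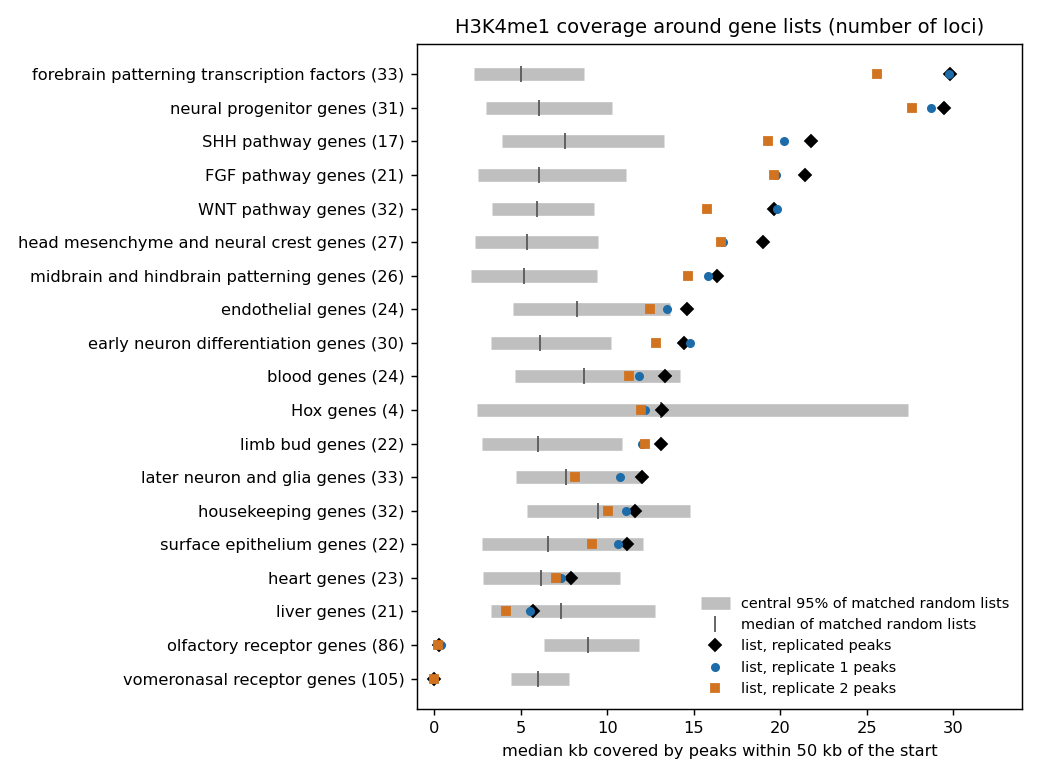
Median kb covered by peaks within 50 kb of the start (x axis) for each of 19 gene lists (y axis, number of loci in brackets), from the replicated list (diamonds), replicate 1 (circles) and replicate 2 (squares), with the median (tick) and central 95% (bar) of 10000 matched random lists. The forebrain and progenitor lists lie at 29.8 and 29.5 kb, right of all others, and the receptor families lie at 0.26 and 0 kb.

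Set directly against lists of other tissues, without matching on gene length, gene density or GC content, the forebrain factors had more of the mark around them. Their median of 29.8 kb exceeded that of liver genes by 24.1 kb and that of heart genes by 21.9 kb, each with an adjusted permutation p of 3e-05. It exceeded limb bud genes by 16.7 kb (adjusted permutation p = 0.0027), blood genes by 16.5 kb (0.0013), the Hox clusters by 16.6 kb (exact permutation test of 33 against 4 loci, 0.014) and midbrain and hindbrain genes by 13.5 kb (0.014). Counting peaks in place of kb ended the call against midbrain and hindbrain, limb bud and blood genes and gave a difference of -0.60 peaks against the Hox clusters. Windows of 100 kb ended the calls against midbrain and hindbrain genes, blood genes and the Hox clusters. The forebrain list holds only transcription factors, while the heart, liver, blood and limb bud lists also hold other kinds of genes. The midbrain and hindbrain list holds such a gene only in Wnt1. Against the heart, liver, blood and limb bud lists, tissue and kind of gene cannot be told apart.

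Across the genome, the gene with the most H3K4me1 was Ccdc85c on chromosome 12 (108203602 to 108275425), with 72.7 kb of the surrounding 100 kb covered and 69.5 ± 1.84 kb in the replicates (SD, n = 2). It was followed by Flrt1 on chromosome 19 (71.7 kb), the Groucho-family corepressor Tle3 on chromosome 9 (65.6 kb) and the ephrin ligand Efna2 on chromosome 10 (65.6 kb). Gnat1 (63.9 kb), Bahcc1 (63.1 kb), Dohh (62.6 kb), Ahdc1 (62.6 kb), the nuclear receptor corepressor Ncor2 (62.1 kb) and Scube1 (61.6 kb) completed the 10 named, from which genes starting within 100 kb of a gene already taken were left out. None of these 10 was in a fixed list.

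Joining peaks at most 1 kb apart gave 111973 domains with a median length of 1.02 kb, of which 1151, or 1.03%, were over 10 kb and held 9.28% of the covered bases. The longest, 86.2 kb, lay inside Gse1 on chromosome 8 at 120481063 to 120567237 and a second of 62.6 kb lay in the same gene at 120321800 to 120384377. A domain of 74.0 kb held the start and nearly all of Ccdc85c (chromosome 12, 108206787 to 108280804). Domains of 62.9 kb inside Msi2 (chromosome 11, 88546674 to 88609524) and 52.4 kb over the start of Notch2 (chromosome 3, 98012721 to 98065152) completed the first 5.

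The 5 peaks of highest signal also lay inside genes. They were in Ncor2 (chromosome 5, 125150465 to 125161283, signal 18.8), Gse1 (chromosome 8, 120496214 to 120501922, 18.5), the WNT co-activator gene Bcl9l (chromosome 9, 44483701 to 44502293, 18.1) and Zfp423, a zinc finger factor of the developing brain. Zfp423 held a pair of them, on chromosome 8 at 87827337 to 87839588 (18.0) and at 87936468 to 87941730 (17.9).

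At loci chosen beforehand, Sox2, a factor of neural progenitors, had 64.9 kb of the surrounding 200 kb covered (62.0 ± 5.58 kb in the replicates, SD, n = 2), Pax6 55.0 kb (51.5 ± 5.37 kb), Otx2 52.8 kb (49.5 ± 4.37 kb) and Fgf8, a signal of the rostral midline, 49.2 kb (44.9 ± 0.81 kb). Foxg1, the telencephalic regulator, had 18.1 kb (17.2 ± 1.94 kb) and Shh, the ventral signal, 12.4 kb (11.7 ± 1.00 kb). These last values lay below that of the heart factor Nkx2-5 (21.7 kb, 19.4 ± 1.13 kb). The blood factor Gata1, on chromosome X, had 15.9 kb and the liver gene Alb 5.29 kb.

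The intergenic DNA between Dlx1 and Dlx2, homeobox genes of ventral forebrain, spans chromosome 2 from 71533982 to 71543407. It held 2 peaks covering 6.30 kb, or 66.9% (5.96 ± 0.22 kb in the replicates). That between Dlx5 and Dlx6 on chromosome 6, from 6868569 to 6877804, held 1 peak of 1.61 kb, or 17.5% (1.31 ± 0.19 kb). Of the Hox clusters, which pattern the trunk and hindbrain, the peaks covered 17.6% (Hoxa), 10.5% (Hoxb), 8.73% (Hoxc) and 17.5% (Hoxd).

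The fourth comparison asked which transcription factor motifs distal peaks held more often than their flanks. Several motifs, of neural and of other factor families, were denser in the peaks once shuffled motifs were subtracted, and no test set neural against other motifs. Matches to the X-box of RFX factors, which act in ciliogenesis and in neural progenitors, numbered 2416 and were denser by a log2 ratio of 0.97, or 0.85 ± 0.34 (SD over 20 chromosomes) after subtracting shuffled motifs. The ASCL E-box, bound by the proneural factor ASCL1 and by muscle bHLH factors, had 0.77, or 0.50 ± 0.05 after subtraction. The ZIC site had 0.96, or 0.45 ± 0.10, and the TEAD site, bound by effectors of Hippo signalling, 0.30, or 0.57 ± 0.07. Each of these exceeded 20 of 20 shuffled motifs.

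Against flanks, the homeodomain core TAATTA had the largest corrected value, 0.93 ± 0.07, above 13 of 13 shuffled motifs, though its raw log2 ratio was 0.02. The peaks had a GC content of 48.3% and the flanks 43.6%, and against random regions matched on GC content the raw ratio was 0.77 and the corrected one 0.89, below the 1.06 of RFX. RFX also led around summits (1.22 against 1.13). Corrected values were 0.48 ± 0.09 for POU, 0.26 ± 0.08 for SOX, 0.20 ± 0.04 for the nuclear receptor site and 0.17 ± 0.06 for OTX, whose raw ratio was -0.16. POU and SOX exceeded 19 of 20 shuffled motifs, the nuclear receptor site 18 and OTX 15. The corrected values of the 9 motifs named so far were above 0 on 20 of 20 chromosomes, with an adjusted sign-flip permutation p of 1.6e-05. This test flips signs over chromosomes and leaves out the spread between shuffled motifs. That spread (SD) was 0.21 for OTX and 0.19 for the nuclear receptor site. The p therefore does not measure whether a motif exceeds other sequences of its composition, here or for the motifs below. Before correction OTX was called lower in the peaks and the homeodomain core was not called. In single replicates the raw homeodomain ratio turned direction. It was 0.05 in replicate 1 (called higher, adjusted sign-flip permutation p = 0.0077) and -0.04 in replicate 2 (called lower, 0.021).

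Of the motifs included for comparison with other tissues, MEF2, of muscle, heart and neurons, had 0.51 ± 0.18 after subtraction and exceeded 20 of 20 shuffled motifs, with a raw ratio of -0.09 and an adjusted permutation p of 1.6e-05. HNF1, of liver, had 0.51 ± 1.31 over 83 matches (adjusted permutation p = 0.018), above 18 of 20 shuffled motifs, with a raw ratio of -0.45. The HNF1 call was lost in replicate 2 alone (0.38), on stronger peaks (0.24) and around summits (0.40). GRHL, of surface epithelium (0.08 ± 0.08, p = 0.00044), GATA, of blood and heart (0.05 ± 0.08, p = 0.020) and the proneural E-box CAGATG (0.04 ± 0.04, p = 0.00029) passed the adjusted permutation test with small values that exceeded only 13, 11 and 12 of 20 shuffled motifs. The raw ratio of GATA was -0.22, called lower, that of GRHL was -0.01 and that of the proneural E-box 0.11. Against GC-matched regions neither GATA (-0.01) nor the proneural E-box (0.02) was called. ETS (0.13 ± 0.47) and CTCF (-0.03 ± 0.67) were not called against flanks (adjusted permutation p = 0.17 and 0.80) and were called higher against GC-matched regions, at 0.36 and 0.40.

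**Figure D4:**
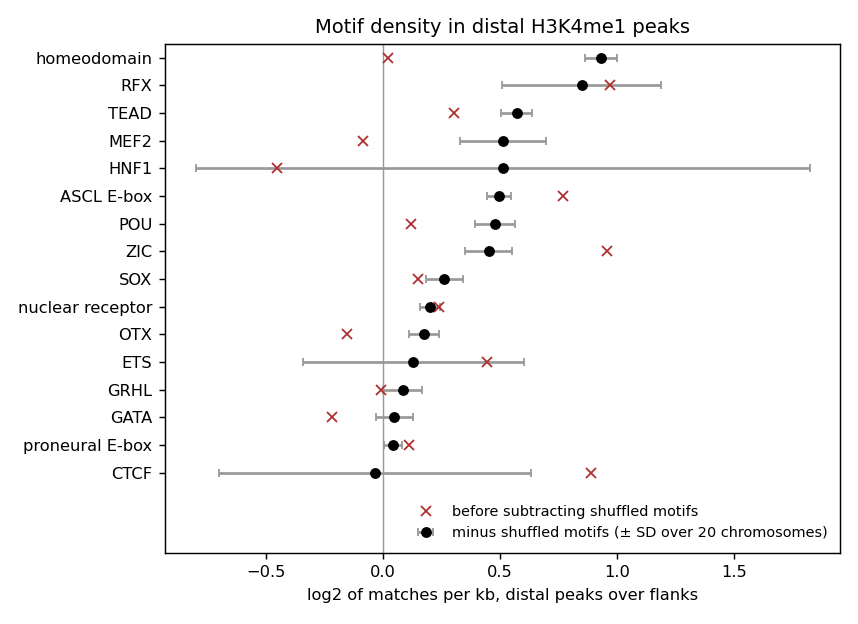
Log2 ratio of motif matches per kb in distal peaks over flanks (x axis) for 16 motifs (y axis), before (crosses) and after (circles, ± SD over 20 chromosomes) subtracting shuffled motifs of the same composition. Homeodomain (0.93) and RFX (0.85) have the highest corrected values, and the homeodomain value before subtraction is 0.02.

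The mark was unevenly spread over chromosomes. On autosomes the replicated peaks covered from 5.35% of bases (chromosome 3) to 10.9% (chromosome 11), with a median of 6.82%. On chromosome X they covered 1.12%, a ratio of 0.16 to the autosome median, and this ratio was 0.17 in replicate 1 and 0.15 in replicate 2. Chromosome X had 13.8 peaks per Mb, against 55.0 on chromosome 3, and 5.80 protein-coding starts per Mb, against 5.50 on chromosome 12, the autosome with the fewest. The median signal of its peaks was 3.02, below the autosomal range of 3.23 to 3.41.

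**Figure D5:**
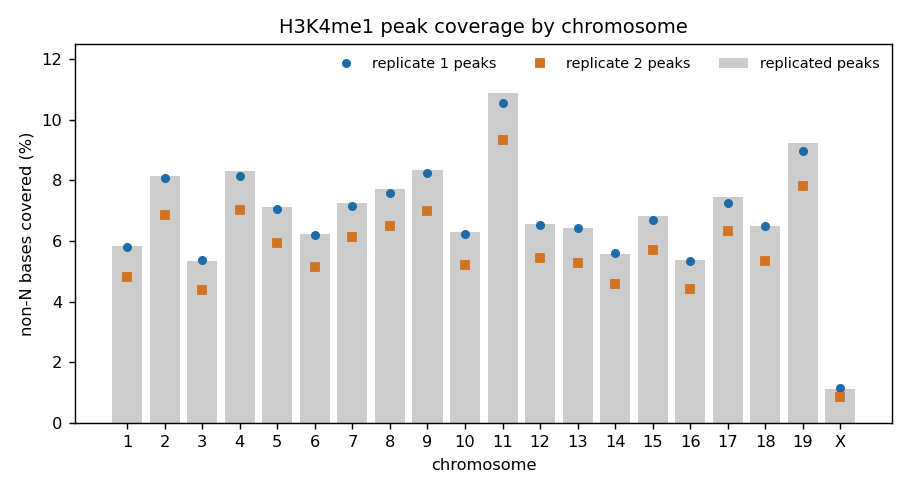
Share of sequenced bases covered by peaks (y axis, %) on each chromosome (x axis), for the replicated list (bars), replicate 1 (circles) and replicate 2 (squares). Chromosome X lies at 1.12%, below every autosome, the lowest of which is at 5.35%.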

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

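Of 555 recalculations of 59 main results, 486 stayed the same, 32 lost the call, 10 gained one, 8 moved and 19 turned direction. For tested results, the same meant the same direction and the same side of the threshold. For counts it meant staying within a set factor, and for other values staying within their spread. Counts and values beyond these limits were labelled moved. Some alternatives could change little. The filter at −log10 q of at least 2 removed 0.97% of the replicated peaks, and shared bases over the union do not depend on the overlap rule. The number that stayed the same is therefore not a measure of robustness by itself. The set of peaks covered by each replicate and the matching on CpG content of the start were chosen after seeing the data. Read depth is unknown, so its effect could not be separated from that of the calling threshold. No paired analysis was possible because the series has 1 group. Leaving out a replicate was not possible for the overlap between replicates. Where a value moved, the cause was not tested. The annotation classes and start profiles kept their calls under each alternative run. So did the forebrain, progenitor, WNT, SHH, FGF and head mesenchyme lists, and the homeodomain call aside from the raw ratio.

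Requiring 50% of both peaks gave shared peaks of 45.9% and 56.9%. Shared bases were 63.3% with −log10 q of at least 2 and 64.5% with equal numbers of peaks, and the correlation of peak heights was 0.55 with that filter. The X ratio was 0.13 on the stronger peaks.

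With GC matching 0 lists were called lower, and with CpG matching 1. GC matching ended the calls of the midbrain and hindbrain (16.3 kb), limb (13.1 kb), endothelial (14.6 kb), olfactory (0.26 kb) and vomeronasal (0 kb) lists, and placed the heart (7.92 kb), epithelial (11.1 kb) and Hox (13.2 kb) lists below their random medians, without a call. CpG matching ended the limb (13.1 kb) and vomeronasal (0 kb) calls, added calls for blood (13.4 kb) and later neurons (11.98 kb), and placed the Hox (13.2 kb) and housekeeping (11.6 kb) lists below. Without matching the limb list (13.1 kb) was not called. Windows of 100 kb ended the limb (21.1 kb) and endothelial (27.7 kb) calls, and those of 10 kb ended the endothelial call (3.52 kb) and added epithelium (3.87 kb), later neurons (3.79 kb) and housekeeping (4.65 kb). By number of peaks the early neuron (10 peaks) and endothelial (13 peaks) lists were not called. The mean ended the endothelial call (15.9 kb) and added housekeeping (16.4 kb). The endothelial call ended on the stronger peaks (10.7 kb), on peaks covered by each replicate (12.03 kb) and without replicate 2 (12.46 to 13.47 kb over single replicates). Stronger peaks added epithelium (10.4 kb) and later neurons (10.3 kb). The Hox median, never called, also fell below its random median on stronger peaks (9.24 kb), on peaks covered by each replicate (11.8 kb), in windows of 100 kb (21.8 kb), by the mean (12.2 kb) and without replicate 2 (11.97 to 12.19 kb over single replicates).

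In windows of 100 kb the forebrain excess over midbrain and hindbrain (14.4 kb), Hox (21.7 kb) and blood genes (13.7 kb) was no longer called. In windows of 50 kb these differences were 13.5, 16.6 and 16.5 kb, and kb in windows of unlike width are not directly comparable. By number of peaks the forebrain excess was 2.5 over midbrain and hindbrain, 2 over limb and 4.83 over blood genes, none called, and -0.60 against Hox.

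Without shuffle correction the homeodomain ratio was 0.0224 and not called. In single replicates it was called in opposite directions, at 0.0536 in replicate 1 and -0.0442 in replicate 2. Also without correction, OTX (-0.16) and GATA (-0.22) were called lower, and ETS (0.44) and CTCF (0.89) were called higher. The uncorrected ratios of MEF2 (-0.0852), HNF1 (-0.45) and GRHL (-0.00997) lay below 0 without a call. Against GC-matched regions the proneural E-box (0.0179) and GATA (-0.00787) lost their calls and ETS (0.36) and CTCF (0.40) gained one. On stronger peaks the proneural E-box (0.0242), GATA (0.0344) and HNF1 (0.24) lost theirs, and around summits GATA (0.0562), HNF1 (0.40) and GRHL (0.0490). HNF1 had 0.38 to 0.44 over single replicates and lost its call without replicate 1. Of 268 recalculations of 104 named genes and loci, 157 moved by more than the spread between replicates. Where the replicated list covered more than either replicate, the farther replicate lay outside that spread by construction. This count therefore does not measure robustness.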

Other observations

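The grouping of genes by family and the comparison of replicate 2 with replicate 1 over gene lists were chosen after values had been seen. Families of protein-coding genes sharing a symbol stem were run through the same list test, 294 families with at least 8 loci. The Sox family of transcription factors (19 genes) had a median of 21.8 kb of H3K4me1 within 50 kb of the start, and the semaphorins, guidance cues of growing axons (20 genes), had 22.7 kb. Both were called higher, with and without GC matching. The cytochrome P450 family (100 genes, 2.42 kb) and the Nlrp family of innate immune and oocyte genes (17 genes, 0 kb) were called lower in both. Without GC matching 6 families were called higher and 7 lower. Those that GC matching ended were Wnt (24.6 kb), the stem Rps, ribosomal proteins together with S6 kinases (14.6 kb), Tmem (11.03 kb) and Slc (9.54 kb) among the higher, and Olfr (0.26 kb), Vmn, Btbd, Skint and Sult (0 kb each) among the lower. With GC matching alone, the genes of the stem Il, interleukins together with their receptors and related genes (82 genes, 4.82 kb), and the chemokine family Ccl (23 genes, 2.11 kb) were called lower. All 294 families were adjusted together, and families are not independent of the fixed lists.

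A peak lay within 5 kb of 79.7% of the 256 CpG-rich starts on chromosome X and of 98.4% of the 9802 on autosomes. For CpG-poor starts the shares were 31.9% of 692 and 55.5% of 10978. These shares were not tested.

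The lower coverage of chromosome X was weighed against repeats, gene content and DNA dose. Repeats alone do not account for it, since peaks covered 1.81% of the bases outside repeats on X and 6.88% on chromosome 16, the lowest autosome. Matching on gene length, density and GC content lowered the autosomal median from 8.02 to 3.33 kb, so these properties go with a large part of the difference, yet the median of X genes, 0.74 kb, lay at percentile 0 of the matched lists (3.02 to 3.65 kb, with as few as 2 genes in the smallest class). If signal values scale with DNA dose, a lower dose in a mixed-sex pool would shift them by a factor of about 0.75. Matching the X peak density needed 0.432 or less on every autosome. At a factor of 0.5 matched autosomal genes kept 1.89 kb (1.66 to 2.13 kb), with each remaining peak at its full width. The scale of the signal value is not stated, and a lower dose could also narrow peaks. How much of the difference comes from dose therefore cannot be told. Silencing of one X in the female embryos may add to the difference, which stays an untested hypothesis, as do reads that the authors' filters removed.

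The second pattern was the high coverage around head mesenchyme and neural crest genes in a forebrain sample, which CpG-rich starts do not account for, since the list stayed at percentile 100 with CpG matching. Mesenchymal cells carried over at dissection may contribute, but the 9 members that encode no transcription factor had a median of 11.7 kb at percentile 94.29, against 21.3 kb for the other members, so this cannot be told with so few genes. Compared with lists matched on coverage and GC content, the list was higher in replicate 2, with a log2 ratio of kb covered of -0.01 at percentile 99.96 (random median -0.13) and, over peaks called in both replicates, a log2 signal ratio of 0.10 at percentile 100 (random median -0.10, adjusted permutation p = 0.0038 over 19 lists). This comparison was chosen after the replicate values of the named genes, Dlx3 and Alx4 of this list among them, had been seen. The permutation p of this list is therefore not independent of those values. Among the other lists the heart signal ratio was higher (0.07, adjusted permutation p = 0.0076), the FGF ratio of kb higher (-0.05, 0.042) and the WNT ratio of kb lower (-0.24, 0.0095), while forebrain factors did not stand apart (signal -0.14, percentile 52.4). The members that encode no transcription factor lay at percentile 95.11 for signal and 28.0 for kb, so more mesenchyme in replicate 2 is neither shown nor ruled out.

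The third pattern was the asymmetry at CpG-rich starts, with 38.3 percentage points more coverage 1.5 kb downstream than upstream. A start in use lying downstream of the annotated 5′ end would leave little of it at genes whose transcript starts all lie within 100 bp, yet at these 2128 genes the difference was 28.9 points and above 0 on 20 of 20 chromosomes. At the 4667 genes without another gene within 5 kb upstream the difference was 49.7 points, with upstream coverage of 18.4% there and 30.02% over all CpG-rich genes, which argues against upstream neighbours as its source. These genes can differ from the others in more than their neighbours, and neighbours downstream were not tested. Deposition of the mark along the transcribed side is a hypothesis that these lists, without expression data, leave untested.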
